A study of Mus musculus with 12 samples.

How the data were processed

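The series holds 12 ChIP-seq libraries of mouse brown adipose tissue, pulled down with anti-HA beads: 4 of HA-RevErbα mice at 4 °C, 4 at 29 °C, and 2 of WT mice at each temperature, all after 1 week. Groups and replicate numbers were taken from the sample titles. The labels do not state that each library is 1 animal, so the p-value on library depth measures only the spread between these libraries. Bowtie2 2.1.0, HOMER 4.10 and build mm9 are named, without roles, in the submitters' processing notes. Peak-calling settings and the treatment of duplicate reads are not given in the sources used here.

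For each library the deposited file was an aligner log with the numbers of reads, of reads not aligned and of reads aligned. Between 2.54% and 7.37% of reads did not align, the highest share being that of WT 4 °C replicate 1, and no read was logged as aligned more than once. Per the file headers, the 2 peak lists were made on pooled libraries, 1 list per temperature, and they carry the annotation of each peak and values of 4 pools. The FPKM deposited by the authors are reads per kilobase of the peak window per M (mega) reads of the pool, with 0.01 added to each value. The test design fixed beforehand allowed for FPKM of genes; these FPKM are peak values and were treated as peak densities. The headers name the difference columns as minus input; they equal the HA-RevErbα FPKM minus the WT FPKM of the same temperature in every row. The peak score of the authors' files equals the reads in the window per 10 M reads of the pool, which for 200 bp windows is 2 times the FPKM within rounding. All peaks are 200 bp wide in the files as deposited. In each list the peaks have at least 3 FPKM more than WT and, within rounding, at least 4 times the WT value, the lowest folds being 3.99 and 3.97. Whether start positions count from 0 or 1 is not given in the sources used here, so coordinates are printed as the files give them.

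Every FPKM value, less 0.01, was a whole multiple of 1 step per pool (100% of values within 0.01 FPKM), which gave the reads in each window and the reads of each pool. The pools held 49.8% (HA-RevErbα 4 °C), 49.2% (HA-RevErbα 29 °C), 43.9% (WT 4 °C) and 39.5% (WT 29 °C) of the aligned reads of their libraries. Which step left out the other reads is not given in the sources used here. The median 4 °C peak rested on 90 reads and the median 29 °C peak on 68, with 6 and 4 in the matching WT pools. In the HA-RevErbα pools 3 reads correspond to 0.235 FPKM at 4 °C and 0.247 at 29 °C. Ratios of 4 °C to 29 °C were computed from these reads and pool sizes, with exact Clopper-Pearson intervals at the 95% level. They cover counting error only, since reads without molecular identifiers are not independent molecules and pools hold no animal-to-animal spread. No p-value was made from reads. Shares have exact Clopper-Pearson intervals.

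Sites were called shared when a 4 °C and a 29 °C peak overlapped by at least 1 bp, and values of shared sites were taken in the window of the 4 °C list. Chance overlap came from 100 shuffles of the 29 °C positions along the covered span of their chromosomes. Scores of shared and unshared sites, their correlation and the highest peak FPKM per gene (on log2(FPKM + 0.5)) were tested with 100000 two-sided permutations. Annotation classes and gene lists were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment at 0.05. Library depth was compared with a two-sided exact permutation test.

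Peaks were assigned to genes by the authors' annotation, through gene IDs. The gene table at hand was of assembly GRCm38.p6, another build than mm9, and was used for names and IDs only. Of the gene IDs, 5447 of 5451 in the 4 °C list and all 1629 in the 29 °C list matched it. The background was its 21027 protein-coding genes with a curated RefSeq transcript. The 17 gene lists (core clock, fatty acid synthesis and SREBP1, cholesterol synthesis and SREBP2, thermogenesis, fatty acid oxidation, triglyceride synthesis and lipolysis, lipid uptake and transport, glucose uptake and glycolysis, TCA cycle and respiratory chain, adipogenic transcription factors, REV-ERB corepressors and partners, and markers of white adipocytes, macrophages, endothelium, skeletal muscle, smooth muscle and pericytes, and nerve and Schwann cells) were fixed before the data were examined. Nrip1 is in 2 of them. Each gene was represented by its highest-scoring site. The percentile of a list's median ratio was taken among 10000 random lists of the same size, drawn from 10 bins of mean HA-RevErbα FPKM, and describes these pools only.

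Named genes followed a rule set before the data were examined. It took members with a peak of the core clock, fatty acid synthesis and thermogenesis lists, up to 12 per list by score, and up to 4 members of every other list. It also took the genes of the 10 highest-scoring sites of each class (shared, 4 °C only, 29 °C only), 1 site per gene, and the 10 shared sites with the largest ratio in each direction.

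Read recovery, ratio intervals, overlaps, gene list tests and permutation tests of medians were tested on simulated data. The correlation, annotation, matched random lists, gene-level, depth and scaling steps were not. From the windows' own mean reads, the right number of reads was recovered in 100% of 13410 windows of every pool. For the ratio of 4 °C to 29 °C over 11227 sites, 95.6% of intervals held the true ratio, and 4.33% of 11027 unchanged sites had an interval that left out 1. Of 50 sites each with true ratios of 0.25, 0.5, 2 and 4, 100%, 100%, 96.0% and 100% had an interval that left out 1. All 500 planted overlaps were found among 2183 positions. For the gene lists near 4 °C peaks, over 21027 genes, a planted list with 16 of 22 members passed in 100% of 200 simulations, and 0.344% of tests of the other lists passed. These simulations gave all other genes the same chance of a peak. In the data single genes had up to 21 peaks, so this share need not hold for the real lists. Random splits of the 2183 scores of the 29 °C list gave a permutation p under 0.05 in 3.00% of cases.

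Alternatives covered the overlap that counts as shared, stricter scores, equal-sized lists, the distance of a peak from the TSS, scales and pseudocounts, and each library left out of the depth comparison. Those for the share of shared sites higher at 4 °C and the wider gene background were added after the data were seen. A search for Rev-Erb response elements was left out because no genome of build mm9 was used here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.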

Results

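Rev-Erbα is a nuclear receptor encoded by Nr1d1 that represses transcription as part of the circadian clock. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in brown adipose tissue, the heat-producing fat of mice. The mice had been housed for 1 week at 29 °C, a thermoneutral temperature for mice, or at 4 °C, a chronic cold challenge. HA-RevErbα mice carried Rev-Erbα with an HA epitope tag, and anti-HA beads were used for the pull-down. They gave 4 libraries at each temperature. Wild-type (WT) mice, put through the same pull-down as background, gave 2 libraries at each temperature. The HA-RevErbα libraries held 32.0 M (mega) aligned reads ± 3.80 (SD, n = 4) at 4 °C and 30.9 M ± 4.68 (SD, n = 4) at 29 °C. This difference of 1.06 M reads lay within the spread between libraries (two-sided exact permutation test over 70 splits, p = 0.714, smallest possible p = 0.0286). The WT libraries held 29.2 and 32.6 M aligned reads at 4 °C and 27.4 and 36.1 M at 29 °C.

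All binding values came from pools of the libraries of 1 genotype and 1 temperature, so none has a replicate check between temperatures. The deposited unit is FPKM, here the read density in a 200 bp peak window and not a level of gene expression. Recovered from the FPKM steps, the HA-RevErbα pools held 63.8 M reads at 4 °C and 60.8 M at 29 °C, and the WT pools 27.1 and 25.1 M. Intervals given with ratios are exact 95% Clopper-Pearson intervals that cover counting error only and leave out variation between animals. Coordinates are those of the authors' files on mouse build mm9, and the nearest gene is the authors' annotation. The TSS (transcription start site) of that gene can be far from the site, for example 250 kb at Hhat and -227 kb at Il12b.

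The first comparison asked how the set of Rev-Erbα sites in the tissue differed between chronic cold and thermoneutrality. The 4 °C list held 11227 HA-RevErbα peaks and the 29 °C list 2183, a ratio of 5.14. Of the 29 °C peaks, 1670 overlapped a 4 °C peak by at least 1 bp, or 76.5% (95% exact interval 74.7 to 78.3). The same 1670 sites, which included those at the clock genes Npas2, Cry1, Nr1d1 and Arntl, made up 14.9% of the 4 °C list (14.2 to 15.5). This left 9557 sites listed at 4 °C only and 513 at 29 °C only. Positions of 29 °C peaks shuffled along their chromosomes overlapped a 4 °C peak in 0.181% of cases on average, and in at most 0.504% over 100 shuffles. When the 4 °C list was reduced to its 2183 highest-scoring peaks, the overlap was 907 sites or 41.5%. No test between temperatures could be made with 1 pooled list each.

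HA-RevErbα read density per read of the pool was higher at 4 °C at most sites, but for windows of the 29 °C list this depended on how the pools were scaled. Over the 1670 shared sites the median FPKM was 12.28 at 4 °C and 6.10 at 29 °C, against 1.48 and 1.01 in the WT pools. The 4 °C to 29 °C ratio had a median of 1.88 (10th to 90th percentile, 1.08 to 2.98) and exceeded 1 at 1533 shared sites, or 91.8%. Its counting interval lay above 1 at 1356 of them, below 1 at 46 and included 1 at 268. In the 9557 windows listed at 4 °C only, the median was 6.60 FPKM at 4 °C and 2.15 at 29 °C, against 1.12 and 1.21 in the WT pools. Of these windows, 8011 still had more HA-RevErbα than WT signal at 29 °C. Both limits seen in the lists (3 FPKM over WT and 4 times WT) were reached at 29 °C by 96 windows. Another 453 fell short of the fold limit only, 1089 of the difference limit only, and 7919 of both. The 513 windows listed at 29 °C only had medians of 5.03 FPKM at 4 °C and 4.37 at 29 °C, against 1.67 and 0.61 in the WT pools. Each list was selected on the signal at its own temperature, and over all 2183 windows of the 29 °C list the share above 1 was 81.8%. Scaling the 29 °C pool so that summed WT reads at shared sites were equal divided every ratio by 1.44 (0.53 on the log2 scale), and 75.7% of shared sites and 61.9% of all 29 °C windows then stayed above 1. This WT factor depended on the windows: it was 1.02 over all 4 °C windows, 0.954 over those listed at 4 °C only, 1.71 over all 29 °C windows and 2.87 over those listed at 29 °C only. With their own factor of 1.71, 996 of the 2183 windows of the 29 °C list, or 45.6% (43.5 to 47.7), stayed above 1. These windows had to reach 4 times the WT 29 °C value, so low WT 29 °C reads were favoured and the factor was raised by selection. In the 4 °C list, selection on low WT 4 °C reads acts the other way. The turn of the majority therefore cannot show how the pools should be scaled.

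**Figure D1:**
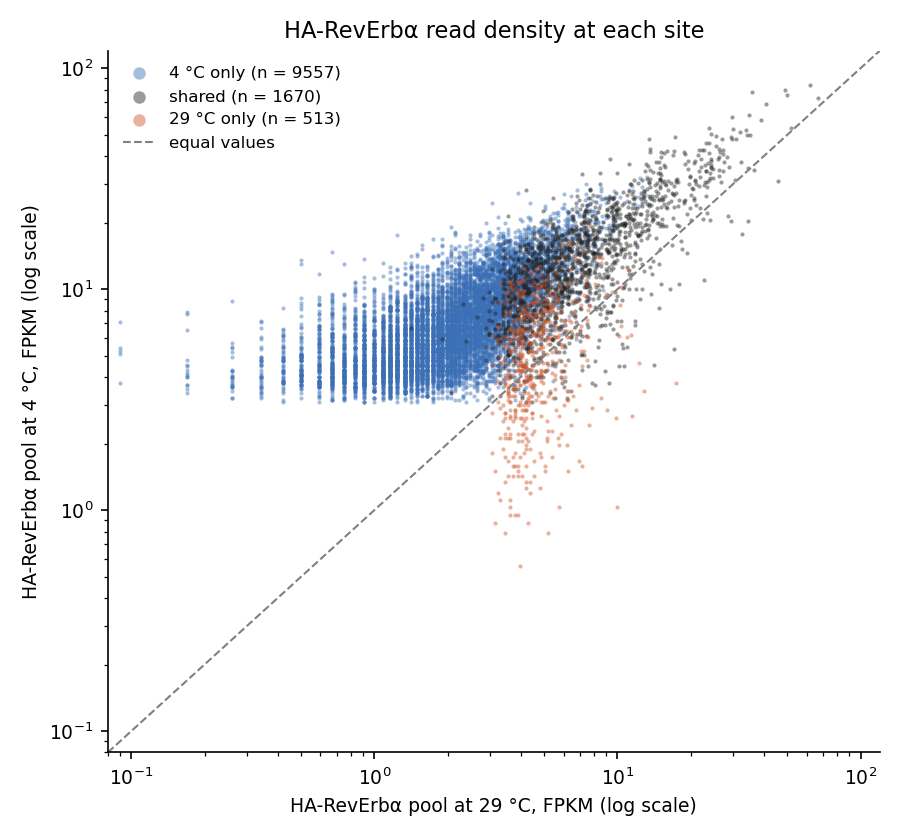
HA-RevErbα read density at each site in the 29 °C pool (x axis, FPKM, log scale) and the 4 °C pool (y axis, FPKM, log scale), coloured by the list that holds the site; the dashed line marks equal values. Most of the 1670 shared sites (91.8%) and 9547 of the 9557 sites of the 4 °C list only lie above the line, and the 513 sites of the 29 °C list only lie on both sides of it.

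The highest-scoring shared sites lay beside clock genes and genes of other functions. The peak score is the authors' own and equals the reads in a window per 10 M reads of the pool. The top shared site, at -1.43 kb from the transcription start site (TSS) of Npas2, a partner of the clock activator BMAL1, scored 168.1 at 4 °C and 123.9 at 29 °C. It spans positions 39249586 to 39249786 of chromosome 1, is annotated as intergenic and had 84.07 FPKM at 4 °C and 61.69 at 29 °C, against 4.06 and 3.0 in the WT pools. An intronic site of the clock repressor Cry1 (chromosome 10, 84624568 to 84624768) had 78.19 FPKM at 4 °C and 35.87 at 29 °C. At the promoter of Nr1d1 itself (chromosome 11, 98636591 to 98636791) the values were 61.57 and 34.80 FPKM, against 2.96 and 4.79 in the WT pools. The other genes of the 10 highest-scoring shared sites were 1700010I14Rik, Abr, Il12b, the cell-cycle inhibitor gene Cdkn1a, Spns1, Dhrs3 and Zbtb16. Among these 10 sites the 4 °C to 29 °C ratio ran from 1.04 at Zbtb16 (interval 0.928 to 1.16) to 2.18 at Cry1 (1.95 to 2.45). The ratios at Zbtb16, Il12b (1.10) and Npas2 (1.36) were below 1 when divided by the WT factor of shared windows, 1.44, and above 1 when divided by that of all 4 °C windows, 1.02. Divided by the factor of all 29 °C windows, 1.71, those at 1700010I14Rik (1.62), Abr (1.51), Cdkn1a (1.69) and Dhrs3 were below 1 as well, and those at Nr1d1, Spns1 and Cry1 were not. The factor of 1.71 is raised by the selection of its windows on low WT 29 °C values.

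Sites listed at 4 °C only reached lower scores than the top shared sites. The 10 highest lay beside Ptpa, Gm15441, Gosr1, Dhrs3, Zfp608, Sh3pxd2b, the clock output gene Hlf, Sh2d2a, Slc41a2 and Gm35135. Their scores ran from 64.3 at Ptpa to 55.8 at Gm35135. At Ptpa (chromosome 2, 30284726 to 30284926, intron) the pools had 32.16 FPKM at 4 °C and 13.17 at 29 °C, a ratio of 2.44 (2.03 to 2.95). At Hlf the values were 28.24 and 7.74 FPKM, a ratio of 3.65 (2.90 to 4.63). Being listed at 4 °C only did not mean a lack of 29 °C signal. At 29 °C, Ptpa (WT 3.20 FPKM), Zfp608 (12.59, WT 3.0), Sh3pxd2b (8.56, WT 1.80) and Sh2d2a (6.84, WT 1.41) also reached both limits seen in the lists. The rest of these 10 sites exceeded WT by more than 3 FPKM there but stayed under 4 times WT, as at Hlf (WT 2.80).

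Sites listed at 29 °C only were led by an intronic site of Mthfd1l, a gene of mitochondrial one-carbon metabolism (chromosome 10, 6343941 to 6344141). It had 17.36 FPKM at 29 °C and 3.77 at 4 °C, a ratio of 0.217 (0.155 to 0.298). Next came Ppp1r12a, a myosin phosphatase subunit, with 12.84 FPKM at 29 °C and 3.46 at 4 °C (ratio 0.269, 0.188 to 0.378). The remaining genes of the top 10 were 2810004N23Rik, 6430573F11Rik, the neurotrophin receptor gene Ntrk2, Slmo2, Usp24, Tbc1d7, Klhdc7a and Ptprg. At Slmo2 the ratio was 1.11 (0.876 to 1.41), so its signal did not differ between the pools beyond counting error although it was listed at 29 °C only. Of all 513 such windows, 114 had an interval below 1, 162 an interval above 1 and 237 an interval that included 1.

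Among shared sites, the ratio was largest beside Hhat, at 6.71 (5.0 to 9.19), with 28.16 FPKM at 4 °C and 4.20 at 29 °C. Sites beside Accsl, Ptk2b, the Notch target Hes1, Tlr2, Mir1904, 1700123J17Rik, Cdca2 and Impa2 were also among the largest, down to 4.21. These ratios were read in the window of the 4 °C peak. At Hes1 this window had 1.41 FPKM at 29 °C, near the WT value of 1.21, while the scores in each list's own window were 13.3 at 4 °C and 8.88 at 29 °C. The smallest ratio was beside Fbrsl1, at 0.312 (0.233 to 0.412), with 5.34 FPKM at 4 °C and 17.12 at 29 °C. The growth hormone receptor gene Ghr had the next smallest, 0.322 (0.235 to 0.435). Wif1, the fat-cell hydroxycarboxylic acid receptor gene Hcar2, Hps1, Marcks, Angpt1, Sh3rf3, Tmem218 and the mitochondrial channel gene Vdac3 followed, up to 0.502.

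A further comparison asked which groups of genes lay beside the sites, for 17 gene lists fixed before the data were examined. Of 21027 protein-coding genes, 4586 (21.8%) were the annotated gene of a 4 °C peak and 1325 (6.30%) of a 29 °C peak. Both lists shared 1216 of these genes, while 3370 had a peak at 4 °C only and 109 at 29 °C only. At 4 °C, 10 of 17 lists held more genes with a peak than the background (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 17 lists). At 29 °C, 8 lists did, but 3 when peaks had to lie within 10 kb, and 3 within 50 kb, of the TSS. These tests describe the 2 lists and not animals. The background was not matched on gene activity in the tissue, open chromatin or the size of gene neighbourhoods. A list that passed is therefore not shown to be a specific target of Rev-Erbα. Every list member with a peak had one at 4 °C, and no member had a peak at 29 °C only. Each gene is represented below by its highest-scoring site, mostly a window selected on 4 °C signal. Of all 11227 windows of the 4 °C list, 10706 had a counting interval above 1, so such an interval does not set a list apart.

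**Figure D2:**
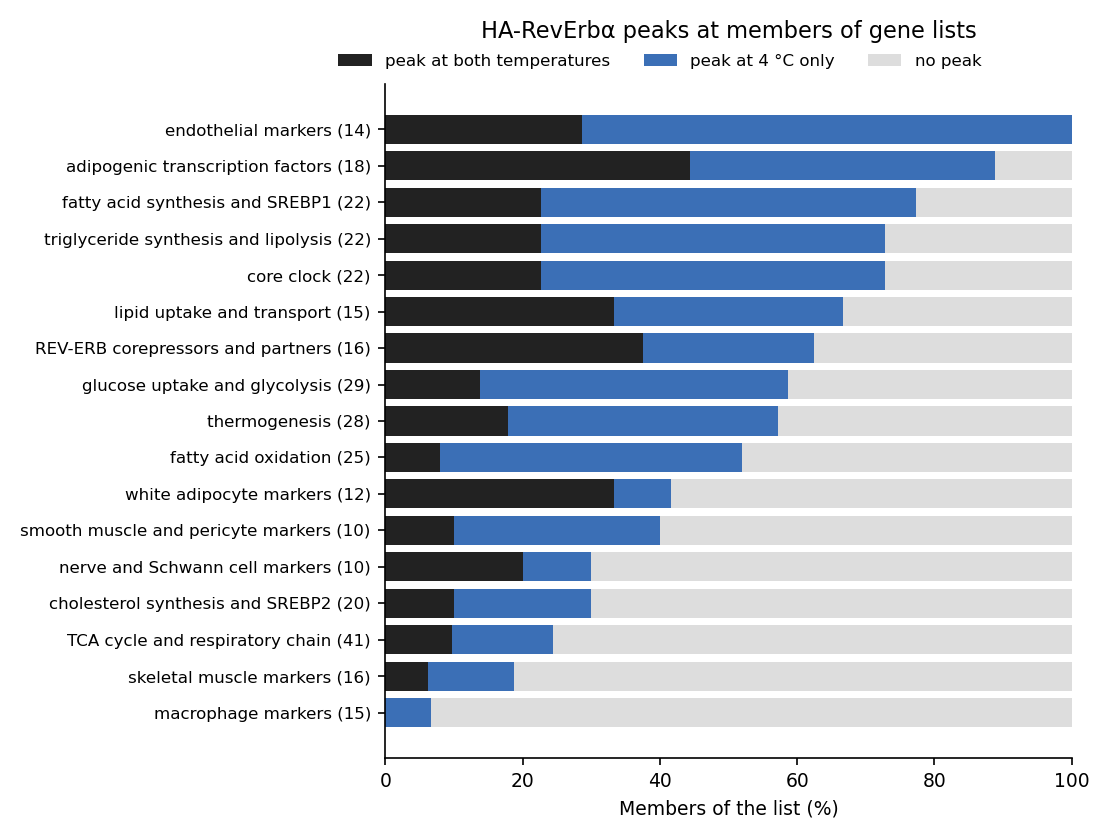
Share of the members of each gene list (x axis, percent; number of members in parentheses) with an HA-RevErbα peak at both temperatures, at 4 °C only, or without a peak. All 14 endothelial markers and 16 of the 18 adipogenic transcription factors had a peak, against 1 of the 15 macrophage markers.

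Core clock genes had peaks at 16 of 22 members at 4 °C (adjusted p = 1.65e-06, Fisher's exact test) and at 5 of 22 at 29 °C (adjusted p = 0.0224). The 5 genes with peaks at both temperatures were Nr1d1, Npas2, Cry1, Nfil3 and Arntl, which encodes the clock activator BMAL1. Genes with peaks in the cold list only included Clock, Per2, Cry2, the PAR bZIP output genes Dbp and Hlf, and the repressor genes Bhlhe40 and Bhlhe41. At the highest-scoring site of each gene the ratio was above 1 at all 16 genes, and only Npas2 was below 1 when divided by the WT factor of shared windows (1.44), but not by that of all 4 °C windows (1.02). Arntl had 48.63 FPKM at 4 °C and 17.28 at 29 °C at an intronic site (ratio 2.82, 2.40 to 3.31). Nfil3, a repressor of PAR bZIP targets, had a promoter site with 28.32 and 13.17 FPKM (ratio 2.15, 1.78 to 2.61). The promoter sites of Clock and Dbp had ratios of 1.97 (1.58 to 2.47) and 2.69 (1.96 to 3.72). At 29 °C the Clock site had 9.88 FPKM against 2.60 in WT, short only of the limit of 4 times WT. Dbp had 4.53 FPKM against 3.20 there. Ratios were 5.07 (3.29 to 8.12) at Per2 and 7.01 (4.38 to 11.8) at Cry2, where the 29 °C pool had 2.07 and 1.65 FPKM against 1.80 and 1.01 in WT, so these ratios rest on 29 °C values near background. The list's median ratio of 2.91 was at the 85.3rd percentile of 10000 random lists matched on signal, whose median was 2.57.

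Genes of fatty acid synthesis and its regulator SREBP1 had peaks at 17 of 22 members at 4 °C (adjusted p = 2.65e-07, Fisher's exact test) and at 5 of 22 at 29 °C (adjusted p = 0.0224). The 29 °C call was lost with peaks within 10 kb of the TSS (adjusted p = 0.446, Fisher's exact test). Sites at both temperatures lay beside Insig1, which retains SREBP in the endoplasmic reticulum, and Scd1, the stearoyl-CoA desaturase gene. Insig1 had 20.01 FPKM at 4 °C and 7.66 at 29 °C (ratio 2.61, 2.05 to 3.35), and Scd1 had 15.30 and 4.70 FPKM (ratio 3.26, 2.42 to 4.46). Elovl5 and Thrsp also had peaks in both lists, but their highest-scoring sites were in the 4 °C list only. Both acetyl-CoA carboxylase genes had sites in the 4 °C list only, with ratios of 3.37 (2.54 to 4.52) at Acaca and 3.47 (2.42 to 5.08) at Acacb. Fasn, the fatty acid synthase gene, was the annotated gene of a site at -48.8 kb with a ratio of 2.33 (1.65 to 3.35). The promoter site of the elongase gene Elovl6 had 10.91 FPKM at 4 °C and 1.65 at 29 °C, where the WT pool had 2.20. Insig2, Me1, Mlxipl, which encodes the glucose-responsive factor ChREBP, and Pcx also had 4 °C sites with intervals above 1. The desaturase gene Fads2, with a shared site and named after its value was seen, was the exception among the 17 genes, with a ratio of 0.827 (0.574 to 1.19). The list's median ratio was 3.34, at the 85.6th percentile of matched random lists.

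Thermogenesis genes had peaks at 16 of 28 members at 4 °C (adjusted p = 0.000123, Fisher's exact test) and at 5 of 28 at 29 °C, which did not pass (adjusted p = 0.0545, but 0.0467 with all protein-coding genes as background and 0.501 within 10 kb of the TSS, Fisher's exact tests). The 5 genes were Ucp1, the uncoupling protein of brown fat, Ppargc1a, a coactivator of mitochondrial biogenesis, Irf4, Otop1 and the adrenergic receptor gene Adrb1. The highest-scoring Ucp1 site lay at -5.80 kb from the TSS (chromosome 8, 85808351 to 85808551). It had 20.55 FPKM at 4 °C and 11.44 at 29 °C, against 1.67 and 2.80 in the WT pools (ratio 1.80, 1.46 to 2.22). Ppargc1a had 14.05 and 3.63 FPKM at -28.1 kb (ratio 3.88, 2.78 to 5.53), and the ratio at Irf4 was 2.90 (2.11 to 4.04). The largest ratios of the list were 12.7 (6.48 to 28.5) beside the adrenergic receptor gene Adrb3 and 10.7 (6.07 to 20.6) beside the elongase gene Elovl3. There the 29 °C pool had 0.75 and 1.08 FPKM, near the WT values of 0.81 FPKM at both sites. Dio2, the thyroid hormone activating deiodinase gene, Ppargc1b, Esrrg, Gk and Kcnk3 also had sites in the 4 °C list only, with ratios of 2.40, 2.34, 3.84, 2.95 and 2.63. The sites of Dio2 and Irf4 lay at 159 and 60.2 kb from the TSS. The median ratio of 3.44 was at the 89.7th percentile of matched random lists.

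**Figure D3:**
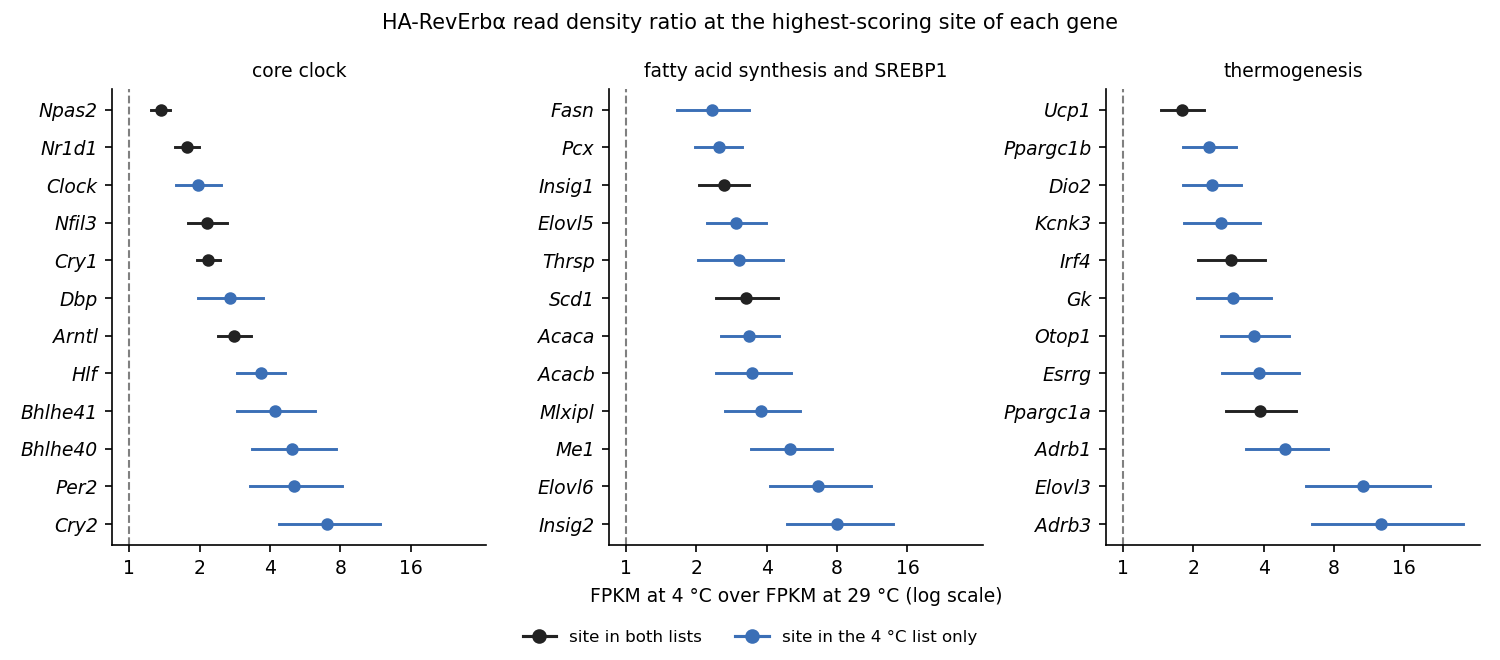
Ratio of HA-RevErbα FPKM at 4 °C to 29 °C (x axis, log scale) at the highest-scoring site of up to 12 genes per list, with exact 95% counting intervals as lines. All 36 intervals lie above 1, as do those of 10706 of the 11227 windows of the 4 °C list; the lowest ratios are those of Npas2 (1.36), Nr1d1 (1.77) and Ucp1 (1.80).

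Further lists of lipid and glucose metabolism passed at 4 °C. Triglyceride synthesis and lipolysis genes had peaks at 16 of 22 members (adjusted p = 1.65e-06), lipid uptake and transport genes at 10 of 15 (0.000515), glucose uptake and glycolysis genes at 17 of 29 (5.28e-05) and fatty acid oxidation genes at 13 of 25 (0.00150), each by Fisher's exact test. At 29 °C the first 2 of these passed with 5 members each (adjusted p = 0.0224 and 0.00985, Fisher's exact tests), while glycolysis with 4 (0.181) and oxidation with 2 (0.711) did not. These 29 °C calls depended on the distance allowed from the TSS in Fisher's exact tests: the uptake list did not pass within 10 kb (adjusted p = 0.405) or 50 kb (0.0674), nor the triglyceride list within 50 kb (0.0535), while glycolysis passed within 10 kb (0.0171). Lpl, the lipoprotein lipase gene, had a shared site at 73.6 kb from the TSS, with 28.08 FPKM at 4 °C and 7.74 at 29 °C (ratio 3.63, 2.89 to 4.61). Angptl4, a lipase inhibitor gene, Fabp4 and Cd36 had sites in the 4 °C list only, with ratios of 2.74, 3.45 and 3.16. At 29 °C the Angptl4 site had 9.47 FPKM against 2.0 in WT and so reached both limits seen in the lists. Fabp4 (7.33 against 5.59) and Cd36 (7.49 against 4.20) stayed under 4 times WT. Lipolysis genes with such sites included Lipe (3.34) and Mgll (3.22), and the lipid droplet gene Plin2 (3.94), and the acyltransferase gene Agpat3 had a shared site (2.92). At Dgat1, named after its value was seen, the ratio of 1.11 had an interval that included 1 (0.831 to 1.48). Pdk4, a kinase that inhibits pyruvate dehydrogenase, led the glycolysis list with 23.69 FPKM at 4 °C and 5.03 at 29 °C (ratio 4.72, 3.57 to 6.32), and Eno1, Hk2 and Pfkl followed. In the oxidation list, high-scoring sites included those of Etfa (2.14, at 90.3 kb from the TSS), Ehhadh (3.04) and Cpt1a (4.74). The median ratios of the triglyceride list, 3.58, and the glycolysis list, 3.85, were at the 98.8th and 98.6th percentiles of matched random lists, and that of the uptake list, 3.30, at the 97.1st. The oxidation list's median of 3.45 was at the 90.6th percentile. Cholesterol synthesis genes with 6 of 20 members (adjusted p = 0.503, Fisher's exact test), among them Hmgcs1, Sc5d, Stard4 and Msmo1, did not pass at 4 °C. TCA cycle and respiratory chain genes with 10 of 41 (0.749), among them Idh3a, Sucla2 and Cox4i1, did not pass either. At 29 °C these 2 lists had 2 and 4 members with peaks and did not pass (0.473 and 0.462). Their median ratios, 2.89 and 2.71, were at the 38.9th and 31.4th percentiles.

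Transcription factors of the adipocyte lineage had peaks at 16 of 18 members at 4 °C (adjusted p = 2.11e-08, Fisher's exact test) and at 8 of 18 at 29 °C (adjusted p = 0.000102, but 0.410 within 10 kb of the TSS). Nfib had a shared site with 32.08 FPKM at 4 °C and 21.89 at 29 °C (ratio 1.47, 1.25 to 1.72), and Klf9 one with a ratio of 2.09 (1.68 to 2.63). The glucocorticoid receptor gene Nr3c1 and Tle3 had their highest-scoring sites in the 4 °C list only, with ratios of 2.07 and 3.18. These sites lay far from the TSS, at 146 kb for Nfib, -106 kb for Klf9, 129 kb for Nr3c1 and 223 kb for Tle3. Genes of REV-ERB corepressors and partner receptors had peaks at 10 of 16 members at 4 °C (adjusted p = 0.000981) and at 6 of 16 at 29 °C (0.00243, but 0.405 within 10 kb, all by Fisher's exact test). Thra, the thyroid hormone receptor gene next to Nr1d1, had 35.77 and 22.05 FPKM at an intronic site (ratio 1.62, 1.39 to 1.89). Nrip1 and Tbl1xr1 had shared sites with ratios of 1.58 and 3.36, and the ratio at Thrb was 5.15. The sites of Nrip1, Tbl1xr1 and Thrb lay at -134, -80.9 and -81.8 kb from the TSS. The median ratios of the factor and partner lists, 3.04 and 3.36, were at the 75.1st and 91.5th percentiles.

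Peaks beside markers of other cell types differed from list to list. Endothelial markers had a peak at 14 of 14 members at 4 °C (adjusted p = 9.22e-09, Fisher's exact test; 5 of 14 and 0.00222 with equal-sized lists) and at 4 of 14 at 29 °C (0.0224, but 0.0782 within 10 kb of the TSS). The highest-scoring were Egfl7, with 22.36 FPKM at 4 °C and 8.23 at 29 °C, the VEGF receptor gene Kdr, with 15.69 and 8.07, Cdh5, with 12.95 and 5.19, and Eng, with 12.48 and 3.38. White adipocyte markers had peaks at 5 of 12 members at 4 °C (adjusted p = 0.234, but 0.0318 within 10 kb) and 4 of 12 at 29 °C (0.0219, but 0.0697 within 10 kb, all by Fisher's exact test), with sites beside Nrip1, Nnat, Adipoq and Retn. At the fifth member, Lep, named after its value was seen, the ratio of 0.851 had an interval that included 1 (0.587 to 1.23). The macrophage list had a peak at 1 of 15 members, Cx3cr1 (adjusted p = 0.307, Fisher's exact test). Skeletal muscle markers had 3 of 16 (Mb, Tnnc2 and Myh4; 1), smooth muscle and pericyte markers 4 of 10 (Notch3, Mcam, Cspg4 and Pdgfrb; 0.314) and nerve and Schwann cell markers 3 of 10 (Pmp22, Mbp and Dbh; 0.524). At 29 °C none of these 4 lists passed, with adjusted p from 0.197 to 1 in Fisher's exact test. The endothelial median ratio of 2.50 was at the 12.8th percentile of matched random lists and the white adipocyte median of 2.35 at the 19.1st. The muscle, pericyte and nerve medians of 2.80, 3.49 and 2.40 were at the 23.8th, 74.2nd and 26.6th percentiles, and Cx3cr1, at 2.48, was at the 10.6th.

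Whether any gene group was more frequent among genes with a peak at 4 °C only was tested directly. Of 4695 genes with a peak in either list, 71.8% had one at 4 °C only. Core clock genes had 11 of 16 (68.8%), fatty acid synthesis genes 12 of 17 (70.6%), thermogenesis genes 11 of 16 (68.8%) and endothelial markers 10 of 14 (71.4%), each with an adjusted p of 1 in Fisher's exact test. No list passed the adjusted threshold, and 2 had an unadjusted p under 0.05: REV-ERB partners (4 of 10, unadjusted p = 0.0354) and white adipocyte markers (1 of 5, unadjusted p = 0.0245), both with fewer 4 °C-only genes than the background and an adjusted p of 0.300 in Fisher's exact test. No list passed with peaks within 10 or 50 kb of the TSS or with equal-sized lists. With equal-sized lists the background was 28.8% of 1860 genes, and the shares of core clock (6 of 11), fatty acid synthesis (5 of 10) and thermogenesis genes (3 of 8) lay above it instead of below. There the triglyceride list had 9 of 14 (unadjusted p = 0.00593, adjusted p = 0.101, Fisher's exact test).

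Most sites lay away from promoters at both temperatures. In the 4 °C list 47.8% of peaks were in introns (interval 46.9 to 48.8), 44.3% were intergenic and 3.82% were at promoters (3.47 to 4.19). In the 29 °C list the shares were 48.1%, 45.7% and 2.98% (2.31 to 3.78 for promoters). Among 4 °C peaks, promoters made up 2.75% of the 1670 shared sites and 4.01% of the 9557 others, which did not pass adjustment over 8 annotation classes (Fisher's exact test, adjusted p = 0.0792). Exons, with 0.539% and 1.16%, had the same adjusted p in Fisher's exact test, and no class passed; these 2 had an unadjusted p under 0.05.

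Shared sites had higher scores than unshared ones within each list. A shared site had to be listed in the other pool too, so this follows in part from the definition and the permutation tests add no separate support. The median score was 24.55 at shared and 13.2 at unshared sites of the 4 °C list, and 12.7 and 8.72 in the 29 °C list (two-sided permutation tests, p = 1e-05 each, the smallest that 100000 permutations can give). Over the 1670 shared sites the scores at both temperatures correlated (Spearman's rho 0.698, Pearson's r on log2 scores 0.736, permutation p = 1e-05 each). This correlation is across sites, which are not independent replicates. At the level of genes, the highest 4 °C peak of the 1216 genes with peaks at both temperatures had a median of 12.87 FPKM, and that of the 3370 genes with a peak at 4 °C only 6.99. The difference of means was 0.83 on the log2(FPKM + 0.5) scale (two-sided permutation test, p = 1e-05). It too is favoured by how the groups were defined, since a gene in both lists also needed a 29 °C peak. The value is also the highest over all 4 °C peaks of a gene, and the number of peaks was not matched.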

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

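The alternatives for the share of shared sites higher at 4 °C and the background of all protein-coding genes were chosen after seeing the data; the other alternatives were planned. The difference in aligned reads per HA-RevErbα library (4 °C minus 29 °C, 1.06 M, for mega) ran from -0.703 to 3.07 M with 1 library left out, with no p under 0.05 in the exact permutation tests. It turned to -0.703 without the deepest 4 °C library, and to -0.257 and -0.0957 without the shallowest and next shallowest 29 °C libraries, since it is smaller than the spread between libraries. At scores of at least 2 times the lowest, the lists held 6794 and 967 peaks, of which 12.6% and 88.4% were shared. The cause of this move was not tested. With equal-sized lists both shares were 41.5%. They are equal by construction, since each list then held 2183 peaks. Leaving out 4 °C peaks can only lower the share of 29 °C peaks that overlap one. The share of shared sites higher at 4 °C moved from 91.8% to 89.9% in the windows of the 29 °C list, 96.8% at the 500 highest scores and 81.8% over all 29 °C peaks. It was 75.7% after scaling to WT reads by 1.44 (the factor was 0.954 to 2.87 over other sets of windows). The share over all 29 °C peaks was 45.6% with the factor of those windows, 1.71, which selection on low WT 29 °C values raises. Scaled shares fell because each ratio was divided by a factor above 1. The remaining shares were taken over other windows or sites, and why these differ was not tested. The number of gene lists that passed at 29 °C moved from 8 to 3 with peaks within 10 kb and to 3 within 50 kb of the TSS; the cause was not tested, and the core clock list passed in each of these settings. Among single list tests, 11 at 29 °C were no longer past the threshold and 2 newly passed it, 1 at 4 °C newly passed it, and the other 156 kept their side. Overlap by 50% of a peak or by centres within 100 or 500 bp, other pseudocounts and scales, annotation tests, and the number of lists passing at 4 °C kept their direction and side of the threshold. No paired analysis was possible because the HA-RevErbα groups share no replicate number and each binding value is 1 value per pool, which also kept WT 4 °C replicate 1, with 7.37% of reads not aligned, from being left out of the binding values. The motif search was not run. Depth limits ratios at weak windows, where the median 4 °C-only window had 26 reads in the 29 °C pool.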

Other observations

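Some genes had many separate sites. Zfp608, a zinc finger gene, was the annotated gene of 21 peaks at 4 °C and 7 at 29 °C. Col4a2 (a basement membrane collagen gene), Klf4 and Plpp3 followed with 17 peaks each at 4 °C and 4, 4 and 5 at 29 °C. Among the listed genes, Tbl1xr1, of the NCoR corepressor complex, had 15 peaks at 4 °C and 1 at 29 °C, Nfia and Thrb had 12 each and 1 and 2, and Arntl had 9 and 3. In the endothelial list, Kdr had 10 peaks at 4 °C and 2 at 29 °C. These genes were named after their counts were seen.

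In the weighing that follows, the tests of pool depth, of WT background at 29 °C and of distance to endothelial genes were chosen after the result was seen. The first pattern is the 5.14 times larger number of peaks at 4 °C. The HA-RevErbα pools differed in reads by a ratio of 1.05, which argues against depth. With the WT 4 °C values in place of the WT 29 °C values, 2.69% of the 4 °C-only windows reached both limits seen in the lists (3 FPKM and 4 times WT) at 29 °C, which argues against WT background. A lower pull-down yield for the whole 29 °C pool stays open, because after raising all 29 °C values by the median ratio of the 500 sites with most reads (1.98), 35.4% of the 4 °C-only windows reached both limits, between the bounds set beforehand. With 1 pool per temperature, such a yield difference cannot be told apart from more Rev-Erbα protein or binding in the cold, which was not tested.

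A second pattern is the 513 windows listed at 29 °C only, whose median FPKM was 5.03 at 4 °C and 4.37 at 29 °C, while the median of HA-RevErbα over WT was 3.13 and 7.57. Their median ratio of 1.09 was below 1 after division by the WT factors of 1.44, 1.71 or 2.87. It stayed above 1 after division by those of all 4 °C windows (1.02) or of the 4 °C-only windows (0.954). The factors of 1.71 and 2.87 are raised by selection on low WT 29 °C values. Since the side of 1 depends on the windows that give the factor, none of these divisions decides the question. With their own WT 4 °C values, 64 of the 513 windows (12.5%) already reached both limits at 4 °C without being listed there. The limits alone therefore do not decide a listing. With the WT 29 °C values in place of the WT 4 °C values, 69.2% reached both limits at 4 °C. A higher WT 4 °C value may thus account for many of these windows. This stays open because the windows had been selected on low WT 29 °C values. Counting error alone was predicted to leave 5% or fewer with an interval below 1, and 22.2% had one (18.7 to 26.1). This cannot decide the question, because the windows had been chosen for being listed at 29 °C and not at 4 °C, which by itself favours low ratios. The range also includes the 20% bound set beforehand, and the intervals treat reads as independent. A difference between animals or temperatures was not tested.

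The third pattern is the presence of peaks beside all 14 endothelial markers at 4 °C, which was 5 of 14 when the 4 °C list was reduced to the size of the 29 °C list (4 of 14 at 29 °C). Broad gene neighbourhoods are argued against, as 11 of the 14 had a peak within 10 kb of the TSS (adjusted p = 1.13e-08, Fisher's exact test; 5.23e-09 to 0.00222 over the alternatives). A larger share of endothelial cells in the cold tissue was predicted to raise the ratio at these genes above that of other genes. The median ratio was at the 12.8th percentile of matched random lists, so no such rise was seen. This cannot exclude a larger share, because the prediction holds only if the peaks came from endothelial cells. Whether Rev-Erbα in endothelial cells of the tissue or open chromatin at these genes in adipocytes gave the peaks was not tested, and the expression of the 14 genes was not measured here.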
